A study of Mus musculus with 30 samples.

How the data were processed

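TCR repertoires were sequenced from total RNA of thymic Treg and Tconv of female mice on a C57BL/6 background, aged 4 to 8 weeks. There are 18 TCR alpha libraries (TCRB-Tg, RAG-Foxp3 and TCRd-Foxp3) and 12 TCR beta libraries (RAG-Foxp3 and TCRd-Foxp3), with 3 replicates in each of 10 groups. RAG-Foxp3 and TCRB-Tg libraries come from individual mice. TCRd-Foxp3 mice received 3 doses of 1 mg tamoxifen, cells were taken 2 weeks after the last dose and sorted on ZsGreen, Foxp3-RFP and CD25, and each library pools 3 mice. Per the labels, 50 to 500 ng of RNA was primed in the TCR constant regions, template switching added a unique molecular identifier, and 3 rounds of PCR followed.

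The deposited files list, for each clonotype, a V call, the CDR3 amino acid sequence, a J call and 2 whole-number columns without a header. The first of these is read as the count of unique molecular identifiers made by the authors' processing and the second as the count of reads behind them, because the labels name such identifiers and the second is at least 2 times the first throughout. Column 4 was used as the count. The clonotype caller and its filters are not given in the sources used here; the build is mm10 per the submitters' processing notes. Alpha libraries hold 371248 to 6861310 reads and 374 to 7624 clonotypes, and beta libraries 1379676 to 9026944 reads and 316 to 1228 clonotypes. A clonotype is a V call, J call and CDR3 amino acid sequence. CDR3 nucleotide sequences were not analysed here. Of 69 TRAV calls, 21 name several segments that the calls do not separate, and these take 29.1% to 55.7% of the alpha counts of a library; they were kept as 1 item each. Positions were taken from RefSeq for 106 of 107 named TRAV segments and for all 39 TRAJ, 21 TRBV and 11 TRBJ segments.

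Counts were summed per segment and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3, limma 3.58.1), with total counts as library size, filterByExpr at its defaults, 1 mean per strain and cell type, and Benjamini-Hochberg adjustment within each locus. All libraries of a chain entered 1 fit. The contrast is the mean over strains of Treg minus Tconv, with each strain's own effect, the interaction, and strain contrasts within a cell type. CDR3 alpha sequences were tested in the same way in the 6 TCRB-Tg libraries. Segments named for Treg against Tconv are those past an adjusted p of 0.05 with the same sign in every strain, up to 8 TRAV, 5 TRAJ, 5 TRBV and 3 TRBJ each way, with all segments of fixed lists; calls whose signs differ between strains are named as such. For strain contrasts up to 3 each way are named, and for CDR3 alpha sequences up to 5 each way by the test and the 3 most abundant of each cell type.

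For 24 per-library measures (CDR3 features, locus position, chain lists and diversity of both chains), Treg and Tconv labels were permuted exactly within strains, in 8000 arrangements for alpha and 400 for beta, and adjusted by Benjamini-Hochberg together. The smallest p is 0.00025 for alpha, 0.005 for beta and 0.1 within 1 strain. Net charge counts K and R against D and E, and hydropathy is the mean at CDR3 positions 6 and 7. TRAJ segments were grouped as 42 and above, 22 to 41, and 21 and below. Diversity was taken at 19175 counts for alpha and 19767 for beta over 100 draws, and overlap over 20 draws, with 4 overlap tests adjusted together. A group at 0 is compared with a floor of 3 counts per library. These bounds and the intervals of single shares and ratios take counts as independent, so they cover counting error and not the number of cells sampled. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

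Groups, tests, naming rules and most alternatives were set before the data were examined. These alternatives were each clonotype counted once, TMM, DESeq2 1.42.0, no filter, clonotypes with 1 count left out, each replicate left out, mouse as a block, invariant NKT and MAIT chains left out, hydropathy over 5 central residues, clonotypes by CDR3 alone, other depths and another overlap index. Others were added after the data were seen: clonotypes under 5% of their highest share in another library left out (low-share copies, with V calls under 5% of another call of the same CDR3 and J), the same with each clonotype counted once, irregular CDR3 beta sequences left out, 2 alpha libraries left out, and 4 TRBV segments left out. Shifts of the median log2 fold change of all items under another scaling are listed where over 0.1 in size, TMM first where both are given. For TRAV, Treg minus Tconv moved by -0.25 over strains (TMM), -0.70 and -0.37 in TCRB-Tg, -0.15 in RAG-Foxp3 (DESeq2) and 0.48 in TCRd-Foxp3 (DESeq2). TCRB-Tg minus the other strains moved by 0.92 and 0.82 in Tconv and 0.24 and 0.29 in Treg, and RAG-Foxp3 minus TCRd-Foxp3 in Treg by -0.16 and -0.60. For TRAJ, Treg minus Tconv moved by -0.16 and -0.21 in TCRB-Tg, -0.11 in RAG-Foxp3 (TMM) and 0.26 and 0.45 in TCRd-Foxp3. TCRB-Tg minus the other strains in Tconv moved by 0.21 and 0.44, and RAG-Foxp3 minus TCRd-Foxp3 in Treg by -0.34 and -0.33. For TRBV, DESeq2 moved Treg minus Tconv by -0.18 over strains, -0.11 in RAG-Foxp3 and -0.23 in TCRd-Foxp3, and RAG-Foxp3 minus TCRd-Foxp3 in Treg by 0.12. For TRBJ, TMM moved Treg minus Tconv by 0.11 in TCRd-Foxp3 and RAG-Foxp3 minus TCRd-Foxp3 in Treg by -0.11, and DESeq2 the same difference in Tconv by 0.11. For CDR3 alpha sequences the shift was -0.74 with TMM and 1.31 with DESeq2.

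Replicate numbers pair Treg with Tconv because the labels give the same mouse or pool number. With shares in ppm and a pseudocount of 50 ppm, the correlation of paired deviations was -0.276 to 0.111 for TRAV, -0.322 to 0.235 for TRAJ, 0.197 to 0.668 for TRBV and -0.593 to 0.732 for TRBJ. Replicates of a group were checked for copies by segment usage: over 60 comparisons of replicate pairs, all loci together, the lowest chi-square per degree of freedom was 89.9. On data simulated with these spreads, edgeR recovered 27.1% of 4-fold changes of TRAV segments, 55.8% for TRAJ, 78.4% for TRBV and 100% for TRBJ, and 46.8% of 16-fold changes of CDR3 alpha sequences, so a segment without a call may differ. Reads per identifier were not used as a measure. No library was left out of the reported values.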

Results

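T cell receptor (TCR) repertoires were measured in CD4+ regulatory T cells (Treg), which express the transcription factor Foxp3, and in conventional CD4+ T cells (Tconv), both sorted from the thymus of mice aged 4 to 8 weeks. The 30 libraries fall into 10 groups of 3. RAG-Foxp3 mice carry a Rag2-GFP reporter beside a Foxp3 reporter, and their cells were sorted from individual animals. TCRd-Foxp3 mice carry a tamoxifen-inducible reporter of TCR delta expression, and each of their libraries is a pool of 3 mice. TCRB-Tg mice carry the DO11.10 TCR beta chain as a transgene with a single functional TCR alpha allele, and were sequenced for TCR alpha alone. TCR alpha libraries held 19175 to 153518 counts, where a count is read as 1 molecular identifier, and TCR beta libraries 19767 to 94011. Alpha totals were 42132 to 100569 in TCRB-Tg Tconv, 19175 to 35985 in TCRB-Tg Treg, 66020 to 101669 in RAG-Foxp3 Tconv, 134449 to 153518 in RAG-Foxp3 Treg, 37702 to 130312 in TCRd-Foxp3 Tconv and 42398 to 112372 in TCRd-Foxp3 Treg. Beta totals were 19767 to 94011 in RAG-Foxp3 Tconv, 31349 to 88376 in RAG-Foxp3 Treg, 70699 to 85789 in TCRd-Foxp3 Tconv and 37299 to 63132 in TCRd-Foxp3 Treg. Counts of a clonotype depend on how many cells were sorted and on how much receptor RNA each held, and cell numbers are not given in the sources used here.

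The first comparison asked which TCR beta V segments Treg use more or less than Tconv. TRBV12-1 took a larger share of the Treg repertoire, and TRBV1 and TRBV31 took smaller shares in TCRd-Foxp3. TRBV12-1 (chromosome 6, 41113567 to 41114067 in mm10) held 3.50% ± 0.517 of beta counts in RAG-Foxp3 Tconv and 6.48% ± 1.19 in RAG-Foxp3 Treg (SD, n = 3). In TCRd-Foxp3 it held 2.62% ± 0.0917 in Tconv and 14.7% ± 11.14 in Treg, and it was higher in Treg in 6 of 6 mice or pools. Without TCRd-Foxp3 Treg replicate 1 the last mean is 8.47%. TRBV1 (chromosome 6, 40891296 to 40891885) went from 16.5% ± 4.01 in Tconv to 14.3% ± 2.62 in Treg of RAG-Foxp3 and from 11.7% ± 2.10 to 4.47% ± 0.680 in TCRd-Foxp3. TRBV31 (chromosome 6, 41557693 to 41558371) went from 17.2% ± 7.495 to 13.2% ± 2.90 and from 14.5% ± 2.36 to 6.71% ± 2.73, and both segments were lower in Treg in 5 of 6 mice or pools. In RAG-Foxp3 the lower means rest on Tconv replicate 3, with 21.2% TRBV1 and 25.7% TRBV31 of 19767 counts. Of that library's counts, 75.3% lay in 99 clonotypes shared with Treg of the same mouse, against 34.8% for Tconv replicate 2. Tconv replicates 1 and 2 held 13.9% and 14.5% TRBV1, and 11.7% and 14.2% TRBV31. Those shares lie within the range of the RAG-Foxp3 Treg libraries, 12.2% to 17.2% and 10.3% to 16.1%.

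Over both strains, 3 of 20 tested TRBV segments passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By edgeR, the log2 fold change of Treg over Tconv was 1.69 for TRBV12-1 (SE 0.30, adjusted p = 3.93e-04), -0.80 for TRBV1 (SE 0.17, adjusted p = 0.00168) and -0.75 for TRBV31 (SE 0.22, adjusted p = 0.0186). TRBV13-2, the family of the DO11.10 beta chain, had a log2 fold change of -0.51 (SE 0.18, edgeR adjusted p = 0.0545) and was lower in 5 of 6. Within TCRd-Foxp3 alone, edgeR called TRBV12-1 (2.49, adjusted p = 1.79e-04), TRBV1 (-1.38, adjusted p = 1.79e-04), TRBV31 (-1.11, adjusted p = 0.00983) and TRBV13-2 (-0.96, adjusted p = 0.00983). In RAG-Foxp3 the same 4 segments each had an adjusted p of 0.962, and no difference between the strains' effects passed edgeR's test, where the adjusted p was 0.141 for TRBV12-1, 0.0559 for TRBV1, 0.329 for TRBV31 and 0.164 for TRBV13-2. None of 11 TRBJ segments passed, with 0 at an unadjusted p under 0.05 by edgeR and 0 calls by DESeq2. Without replicate 3 of each group, 1 TRBV segment was called and TRBV1 (-0.74) and TRBV31 (-0.60) were not. TRBV31 also lost its call when each distinct clonotype was counted once, where its log2 fold change was -0.34.

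**Figure D1:**
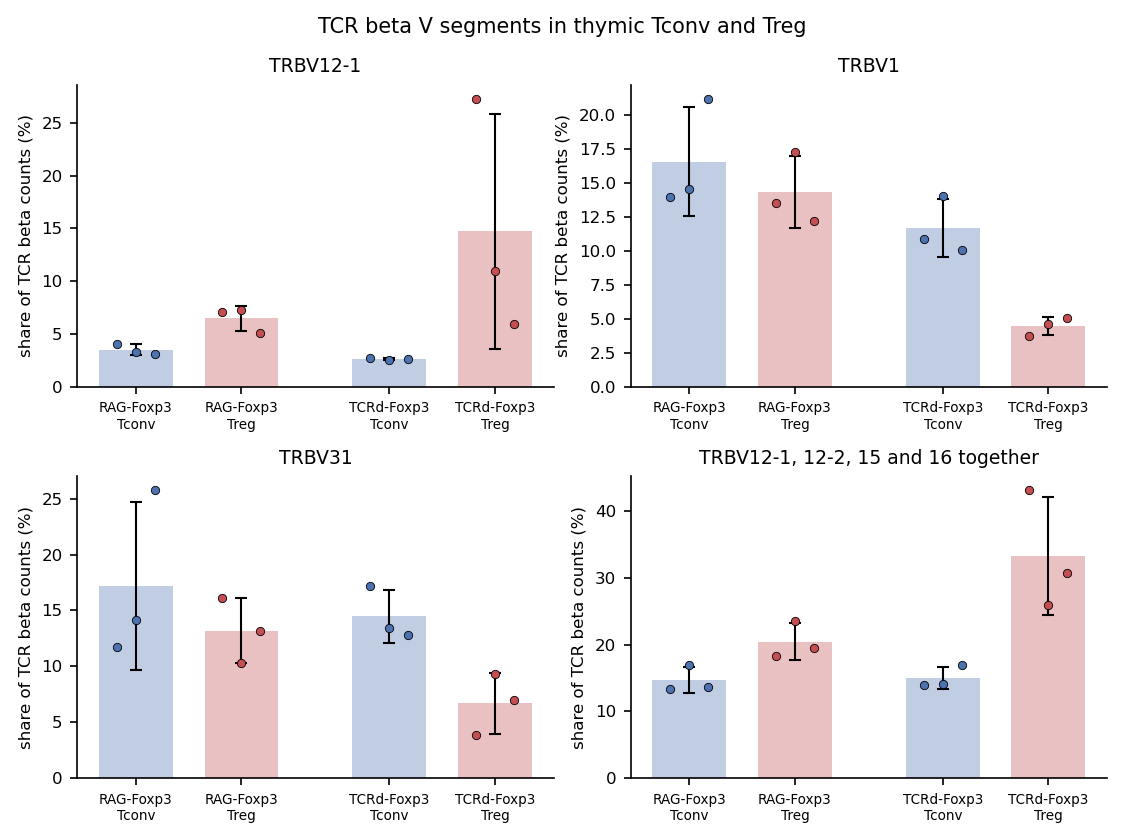
Shares of TCR beta counts (y axis, percent) of TRBV12-1, TRBV1, TRBV31 and the 4 listed V segments together, in Tconv (blue) and Treg (red) of 2 strains; points are the 3 libraries of a group, bars the mean and whiskers the SD. TRBV12-1 reaches 27.3% in 1 TCRd-Foxp3 Treg library and lies above the Tconv libraries of its strain in all 6 Treg libraries.

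TRBV12-1, TRBV12-2, TRBV15 and TRBV16 belong to families that endogenous superantigens delete in mouse strains expressing the MHC molecule I-E, which C57BL/6 mice lack. Together these 4 segments made up 14.6% ± 1.96 of beta counts in RAG-Foxp3 Tconv and 20.4% ± 2.79 in Treg, and 14.97% ± 1.67 in TCRd-Foxp3 Tconv and 33.3% ± 8.82 in Treg (SD, n = 3). The list was higher in Treg in 6 of 6 mice or pools, by 12.03 percentage points on average. The exact two-sided permutation test within strains gave the smallest p it can (0.005, adjusted 0.040 over 24 measures by Benjamini-Hochberg). TRBV12-1 contributed 7.54 points, TRBV15 1.87, TRBV12-2 1.48 and TRBV16 1.14. Single TCRd-Foxp3 libraries weigh on each: without Treg replicate 1 TRBV12-1 contributes 4.41 and TRBV16 0.674, without Treg replicate 3 TRBV15 contributes 0.896 and TRBV12-2 0.774, and without Tconv replicate 1 TRBV15 contributes 1.03. Among these, edgeR called TRBV12-1 alone; its adjusted p was 0.480 for TRBV12-2, 0.480 for TRBV15 and 0.489 for TRBV16. With Treg and Tconv paired by mouse, the exact sign-flip test gave the smallest p it can (0.0313), which did not pass adjustment over 24 measures.

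CDR3 beta loops of Treg carried less negative charge than those of Tconv. Mean net charge per CDR3 rose from -0.736 ± 0.0734 to -0.581 ± 0.0419 in RAG-Foxp3 and from -0.713 ± 0.0271 to -0.506 ± 0.0540 in TCRd-Foxp3 (SD, n = 3). The mean difference of 0.181 was positive in 6 of 6 mice or pools (exact permutation p = 0.005, the smallest possible, adjusted 0.040). Without the 4 listed V segments it was 0.0941, which no longer passed. Paired by mouse, the exact sign-flip test gave its smallest p here too (0.0313), which did not pass adjustment. For CDR3 beta loops with a cysteine inside the loop, the Treg minus Tconv difference was -4.74 percentage points (exact permutation p = 0.025, adjusted 0.120, lower in 5 of 6). For TRBV13-2 as a share of counts it was -3.35 points (exact permutation p = 0.035, adjusted 0.140, lower in 5 of 6). CDR3 beta length differed by -0.165 amino acids (lower in 5 of 6) and hydropathy at positions 6 and 7 by -0.0140 (3 of 6 each way), with exact permutation adjusted p values of 0.342 and 0.967.

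For TCR alpha, the clearest difference was the chain of invariant natural killer T (NKT) cells, a lineage that recognises lipids on CD1d with an alpha chain of TRAV11 or TRAV11D (chromosome 14, 53519303 to 53519859 and 52824357 to 52824913) joined to TRAJ18. This chain held 9.82% ± 8.77 of alpha counts in TCRB-Tg Tconv and 0.0462% ± 0.0103 in TCRB-Tg Treg (SD, n = 3). In RAG-Foxp3 it held 0.380% ± 0.346 in Tconv and 0.107% ± 0.184 in Treg, which without replicate 3 is 0.197% and 0.00130%, and in TCRd-Foxp3 1.19% ± 0.118 in Tconv and 0 counts in 3 Treg libraries. A count of 0 there allows up to 0.00488% on average, at 3 counts per library. The share was lower in Treg in 9 of 9 mice or pools, with a mean difference of -3.74 percentage points (exact permutation p = 0.0005, adjusted 0.012). TCRB-Tg Tconv replicate 2 weighs most in this value with 19.8% of its counts (95% Wilson interval 19.4% to 20.2%, for counting error alone, against 3.26% and 6.41% in the other 2 libraries). Without it the TCRB-Tg Tconv mean is 4.84%, and without replicate 2 of each group the difference is -2.10 points. Paired by mouse, the exact sign-flip test gave the smallest p it can (0.00391), which did not pass adjustment over 24 measures.

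Among TRAV segments, edgeR called 4 of 67 over the 3 strains, all lower in Treg, with 17 at an unadjusted p under 0.05. The call for TRAV11 and TRAV11D, which the files do not separate, had the lowest adjusted p (2.47e-07), and their combined share was lower in Treg in 7 of 9 mice or pools. It was 9.87% ± 8.75 in TCRB-Tg Tconv against 0.0462% ± 0.0103 in Treg, 0.731% ± 0.461 against 0.703% ± 0.508 in RAG-Foxp3, and 1.57% ± 0.458 against 0 in TCRd-Foxp3, where Treg were at least 323-fold lower by the floor of 3 counts per library. Without replicate 2 the TCRB-Tg Tconv mean is 4.92% and the RAG-Foxp3 Treg mean 0.423%. The strains' effects on TRAV11 with TRAV11D differed (edgeR interaction, adjusted p = 6.98e-05). The other 3 edgeR calls had opposite signs in different strains and were at 0 in 3 of 3 TCRB-Tg Treg libraries: TRAV13D-1 (adjusted p = 0.0187), TRAV4N-3 (adjusted p = 0.0220) and a call that names TRAV13-1 with 6 close relatives (adjusted p = 0.00171). Against TCRB-Tg Tconv they were at least 12.2-fold, 5.64-fold and 26.6-fold lower. These bounds cover counting error alone: the TCRB-Tg Treg libraries hold 395 to 496 clonotypes, so a count of 0 can also follow from few cells. In TCRd-Foxp3, TRAV4N-3 also went from 0.626% ± 0.184 to 0.0323% ± 0.0293 (0.0154% without Treg replicate 1) and the TRAV13-1 group from 3.17% ± 1.04 to 0.927% ± 0.845 (0.538% without Treg replicate 1). Other settings changed the number of TRAV calls: DESeq2 made 14, a fit paired by mouse 2, a fit without replicate 1 made 1, and none remained once low-share copies of clonotypes abundant in another library were left out and each clonotype was counted once.

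TRAJ28 (chromosome 14, 54191661 to 54191725) was the single call among 39 TRAJ segments (edgeR adjusted p = 0.0112, 2 segments at an unadjusted p under 0.05), and its direction differed between strains (interaction adjusted p = 3.38e-04). It held 0.901% ± 0.671 of counts in TCRd-Foxp3 Tconv and 2 counts in the 3 TCRd-Foxp3 Treg libraries, a ratio of pooled shares of 1012 with a 95% exact counting interval of 280 to 8362, which was 454 without TCRd-Foxp3 Tconv replicate 3 and 1542 without replicate 1. In TCRB-Tg it went from 1.14% ± 0.215 in Tconv to 2.70% ± 0.908 in Treg and in RAG-Foxp3 from 0.760% ± 0.459 to 1.06% ± 0.488, and it was higher in Treg in 5 of 9 mice or pools. The mean call was lost in a fit paired by mouse, without replicate 1, without replicate 2, without replicate 3, and with each clonotype counted once, where the log2 fold change was -0.83. RAG-Foxp3 Tconv replicate 3 and TCRd-Foxp3 Treg replicate 3 shared 58 alpha clonotypes that held 23.5% and 67.3% of their counts, and without those 2 libraries edgeR called 2 TRAJ segments.

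**Figure D2:**
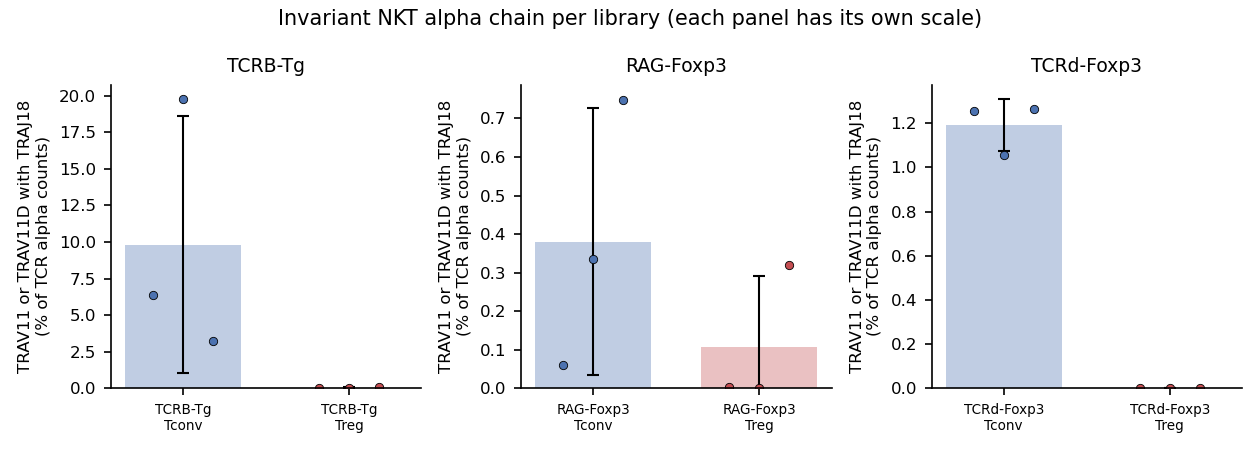
Share of TCR alpha counts (y axis, percent) with TRAV11 or TRAV11D joined to TRAJ18, in Tconv (blue) and Treg (red) of each strain; points are the 3 libraries of a group, bars the mean and whiskers the SD, and each panel has its own scale. The 3 TCRB-Tg Tconv libraries hold 6.41%, 19.8% and 3.26%.

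The position of rearrangements along the TCR alpha locus and the character of CDR3 alpha were compared next, and none of these measures passed adjustment over 24 measures. The mean TRAJ number was 0.189 higher in Treg (exact permutation adjusted p = 0.874, higher in 6 of 9). TRAJ22 to TRAJ41, in the middle of the locus, held 2.56 points more in Treg (higher in 7 of 9), and for the segments 3' of them the difference was -2.78 points (lower in 6 of 9), each at an adjusted permutation p of 0.485. Without invariant NKT chains, whose TRAJ18 lies among the latter, the 2 differences were 0.766 and -0.631 points. In TCRB-Tg the middle segments went from 42.2% ± 3.12 in Tconv to 52.0% ± 3.29 in Treg (exact permutation p = 0.1, the smallest 3 libraries against 3 can give), and without these chains from 46.9% ± 1.28 to 52.0% ± 3.30. V segments of families 17 to 21, nearest the J segments, differed by 0.560 points (higher in 7 of 9, permutation adjusted p = 0.485). Hydropathy at CDR3 positions 6 and 7 was 0.121 higher in Treg (higher in 5 of 9, permutation adjusted p = 0.300), net charge 0.0526 higher (6 of 9, permutation adjusted p = 0.342), and CDR3 length differed by -0.0611 amino acids (lower in 6 of 9, permutation adjusted p = 0.485). The sign of the TRAJ number difference turned to -0.301 with each clonotype counted once and to -0.0882 without invariant NKT chains, that of length to 0.0164 without invariant NKT chains, and that of hydropathy to -0.0311 over the central 5 residues. V calls that name a segment shared with the TCR delta locus differed by 1.56 points (higher in 4 of 9, permutation adjusted p = 0.607), and no listed member passed edgeR's test: TRAV16D/DV11 went from 0.576% to 3.99% in TCRB-Tg and was higher in Treg in 8 of 9 (edgeR adjusted p = 0.192), and TRAV15D-1/DV6D-1 was lower in 9 of 9 (edgeR adjusted p = 0.129). The alpha chain of mucosal-associated invariant T cells, TRAV1 with TRAJ33, had 0 counts in all 18 libraries, which allows up to 0.00195% to 0.0156% per library.

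TCRB-Tg mice carry the same transgenic beta chain. Their TCR beta was not sequenced, so any other beta chain in these cells was not measured. Single CDR3 alpha sequences recurred between these mice and could be tested one by one. Many differed in abundance between Treg and Tconv: of 351 tested, edgeR called 28 higher and 257 lower in Treg, with 286 at an unadjusted p under 0.05, and DESeq2 called 300. Of the 257 lower ones, 229 had 0 counts in all 3 Treg libraries. Tconv libraries held 5154 to 6113 distinct CDR3 sequences and Treg libraries 293 to 367. The excess of lower over higher calls can therefore also follow from few Treg cells. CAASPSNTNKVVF (TRAJ34, mainly TRAV14D-1) held 0.771% ± 0.291 of Tconv counts and 0 in Treg, at least 63.5-fold lower (SD, n = 3, edgeR adjusted p = 0.00192). Such bounds cover counting error alone: the Treg libraries hold 395 to 496 clonotypes, so a count of 0 can also follow from few cells. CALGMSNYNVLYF, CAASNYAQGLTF and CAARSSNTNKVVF were at least 35.01-fold, 32.8-fold and 32.0-fold lower in Treg. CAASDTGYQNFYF held 0.553% ± 0.692 in Tconv and was at least 45.6-fold lower, or 12.6-fold without Tconv replicate 3. In the other direction, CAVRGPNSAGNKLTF (TRAV1 with TRAJ17) rose from 0.00133% ± 0.00230 in Tconv to 0.641% ± 0.325 in Treg (log2 fold change 8.52, SE 1.75, edgeR adjusted p = 0.00338). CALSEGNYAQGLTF (8.10), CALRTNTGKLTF (7.67) and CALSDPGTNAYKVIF (7.31) followed. In Tconv these 4 were found in replicate 1 alone, with 4 to 11 counts, and without that library they were at least 114-fold, 169.8-fold, 112.9-fold and 117-fold higher in Treg. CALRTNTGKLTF (6.56) and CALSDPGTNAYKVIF (6.37) lost their calls without replicate 3 of both groups. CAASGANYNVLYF had 271 counts in Treg and 1 in Tconv (ratio of pooled shares 736, 95% exact interval 131 to 29189, and 363 without Treg replicate 3). That 1 count lies in Tconv replicate 2, and without this library the sequence was at least 102-fold higher in Treg. The most abundant sequences found in all 3 mice were, in Tconv, the invariant NKT sequence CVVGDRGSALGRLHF (9.50% ± 8.56), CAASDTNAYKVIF (1.68% ± 0.830) and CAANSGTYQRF (0.878% ± 0.145), and in Treg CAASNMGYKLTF (2.34% ± 1.39), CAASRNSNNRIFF (1.65% ± 1.30) and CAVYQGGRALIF (1.47% ± 0.931).

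Tested sequences covered 46.0% of TCRB-Tg Tconv counts and 35.7% of Treg counts. At equal depth, 46.6% to 63.5% of the counts of a TCRB-Tg Treg library had a clonotype also found in TCRB-Tg Tconv replicate 1. For Tconv replicates 2 and 3 it was 24.1% to 31.2%. Of the clonotypes such pairs share, 37.6% to 52.6% differed at least 20-fold in share. Clonotypes were thus found in libraries of both cell types, but carry-over between libraries is not excluded as a source. In a fit paired by mouse, 5 sequences were called, 2 higher and 3 lower in Treg, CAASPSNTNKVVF, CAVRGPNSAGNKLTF and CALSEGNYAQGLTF among them; the last 2 lost their calls without a filter on low counts. In Tconv, 1600 of 11325 CDR3 alpha sequences were found in all 3 mice and held 69.8% of counts; in Treg, 100 of 652 were, with 42.3% of counts. Without a filter on low counts 874 sequences were called, and without replicate 2 of both groups 458.

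Repertoire diversity was compared at equal count totals, 19175 for alpha and 19767 for beta. Cell numbers, which are not given, and reads per count, 11.4 to 106 in alpha libraries, were not matched. TCRB-Tg Treg held far fewer alpha clonotypes than Tconv, 422 ± 47.8 against 4905 ± 258 (SD, n = 3). These Treg libraries hold 395 to 496 clonotypes in all, so the difference cannot be separated from the number of cells sorted. TCRd-Foxp3 Treg held 413 ± 169 against 1088 ± 557, and RAG-Foxp3 Treg 1041 ± 256 against 1006 ± 532. Over the 3 strains the difference was -1708 clonotypes, lower in Treg in 7 of 9 mice or pools (exact permutation p = 0.0133, adjusted 0.0795). It did not pass adjustment, but did so with low-share copies left out (-1727), with clonotypes defined by CDR3 alone (-1467) and without the 2 libraries that shared abundant clonotypes (-1781). Beta clonotypes differed by -125 (lower in 5 of 6, exact permutation adjusted p = 0.567). The 10 most abundant clonotypes held 5.47 points more alpha counts (higher in 7 of 9) and 5.44 points more beta counts (higher in 5 of 6) in Treg, and normalised Shannon entropy was lower by a difference of -0.0427 for alpha (7 of 9) and -0.0465 for beta (5 of 6). None of these 4 passed (exact permutation adjusted p = 0.342 for all but beta entropy, 0.300).

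**Figure D3:**
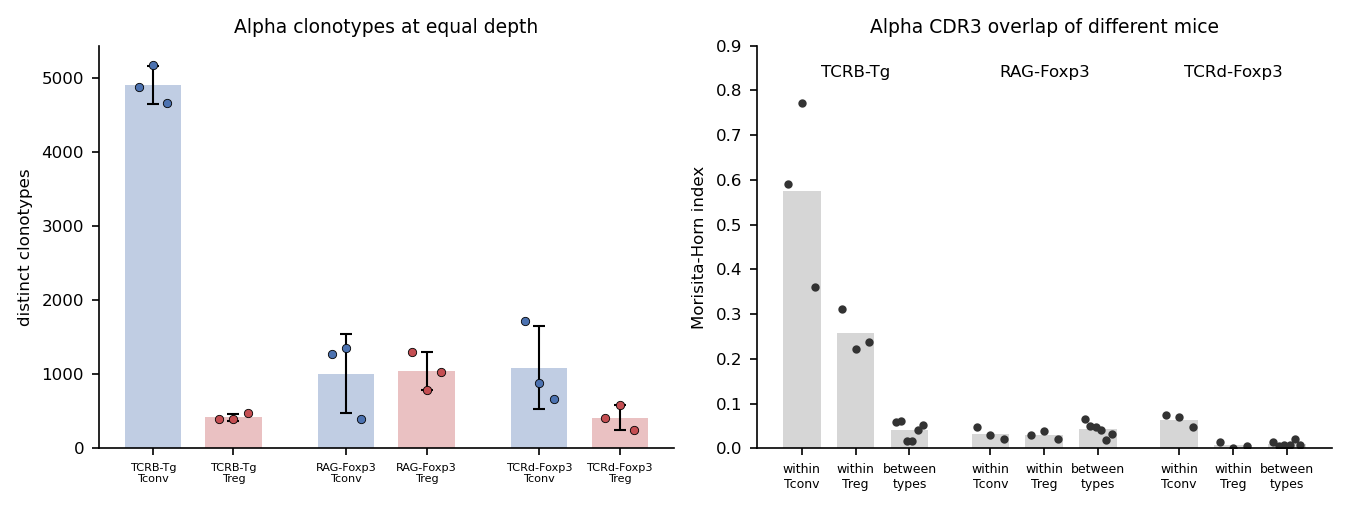
Left, distinct TCR alpha clonotypes at 19175 counts (y axis) in Tconv (blue) and Treg (red) of each strain, with 3 libraries per group as points, the mean as a bar and the SD as whiskers. Right, Morisita-Horn index of CDR3 alpha sequences (y axis) between libraries of different mice of a strain, with each pair as a point and the mean as a bar; TCRB-Tg pairs within Tconv average 0.574 and pairs between cell types 0.0414.

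Overlap was compared between and within mice. Between different TCRB-Tg mice, the Morisita-Horn index of CDR3 alpha was higher within a cell type than across types. It averaged 0.574 within Tconv, 0.257 within Treg and 0.0414 between Tconv and Treg. The Tconv pairs gave 0.590, 0.772 and 0.361, the last being the pair without replicate 1. Abundant sequences weigh most in this index, and the invariant NKT sequence held 6.12%, 19.2% and 3.15% of counts in the Tconv libraries. In Treg it held at most 0.0579%. The invariant NKT sequence was the most abundant clonotype of each Tconv library, ahead of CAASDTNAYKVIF with a mean of 1.68%. It therefore weighs most in the index within Tconv, while the index within Treg does not rest on it. The index was not taken without that sequence, so how much of the Tconv values would remain is not known. The index within minus between cell types was 0.374 in TCRB-Tg, -0.0107 in RAG-Foxp3 and 0.0247 in TCRd-Foxp3. Over the 3 strains it was 0.129 (exact permutation p = 0.012, adjusted 0.048 over 4 overlap tests), which rests on TCRB-Tg and did not pass with low-share copies left out (0.133) or as the percentage of distinct sequences shared (0.672 points). For beta the index was at most 0.00425 on average in any group, with a difference of 0.00187 (exact permutation p = 0.180, adjusted 0.259). Within the same mouse, the percentage of Treg counts whose clonotype also occurred in Tconv did not pass a test against other mice of the strain. For alpha the difference was -4.20 points (exact permutation p = 0.375, adjusted 0.375), with 38.7% ± 21.5 in the same mouse and 35.4% ± 14.4 in other mice in TCRB-Tg, 6.60% ± 6.21 and 8.48% ± 10.3 in RAG-Foxp3, and 2.49% ± 2.32 and 16.5% ± 15.9 in TCRd-Foxp3. Single libraries move it, to -9.42 without TCRB-Tg Treg replicate 1, -0.781 without TCRB-Tg Treg replicate 3, and -2.79 to -2.27 without TCRB-Tg Treg replicate 2, RAG-Foxp3 Treg replicate 1, TCRd-Foxp3 Treg replicate 1 or TCRd-Foxp3 Tconv replicate 3. For beta it was 4.76 points (exact permutation p = 0.194, adjusted 0.259), from 13.8% and 23.0% in RAG-Foxp3 mice 2 and 3 against 0.455% in mouse 1 and 0.971% ± 1.54 across mice. It is 1.89 or 2.07 without RAG-Foxp3 Treg or Tconv replicate 3 and 8.06 or 7.51 without RAG-Foxp3 Treg or Tconv replicate 1. In TCRd-Foxp3 the same pool had 0.00621% ± 0.00168 and other pools 1.93% ± 4.06, of which most came from 1 pair, Treg replicate 1 with Tconv replicate 3 (10.2%). The mean of other pools is 0.347% without the first and 0.133% without the second, and all 26 clonotypes the 2 libraries share differ at least 20-fold in share.

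Strains were compared within each cell type. TCRB-Tg mice carry the DO11.10 beta transgene and a single functional TCR alpha allele. Their T cells used TRAV14D-1 and TRAJ21 more than the mean of the other strains in both cell types. TRAV14D-1 (chromosome 14, 52855665 to 52856166) held 16.2% ± 4.27 of TCRB-Tg Tconv counts against 2.43% ± 1.27 in RAG-Foxp3 and 2.23% ± 0.570 in TCRd-Foxp3 Tconv (SD, n = 3), and 9.96% ± 0.305 of Treg counts against 2.43% ± 0.935 and 0.4997% ± 0.819. Its log2 fold change was 2.8 in Tconv (edgeR adjusted p = 0.0443) and 3.18 in Treg (0.0111). TRAJ21 held 9.24% ± 1.14 and 9.51% ± 1.07 of TCRB-Tg Tconv and Treg counts and at most 4.69% on average in other groups (log2 fold changes 1.29 and 1.47, edgeR adjusted p = 0.0321 and 0.0100). TRAV7N-6 was higher in TCRB-Tg Tconv with 8.69% ± 1.45 (log2 fold change 4.36, edgeR adjusted p = 0.0203). So were TRAJ34 (1.9, edgeR adjusted p = 0.0232) and TRAV11 with TRAV11D (3.20, edgeR adjusted p = 0.0179), while TRAV13D-1 was lower (-3.68, edgeR adjusted p = 0.0331). TRAV11 with TRAV11D held 6.57%, 19.8% and 3.26% of the TCRB-Tg Tconv libraries. Nearly all of it was the invariant NKT chain, with 6.41%, 19.8% and 3.26%. In Treg, TRAJ28 and TRAV7-6 were also higher in TCRB-Tg (edgeR adjusted p = 6.27e-05 and 0.0111). For TRAJ28 the call rests on TCRd-Foxp3 Treg with 2 counts, as the share was 2.70% ± 0.908 in TCRB-Tg and 1.06% ± 0.488 in RAG-Foxp3 Treg. TRAV7-6 held 0.449% ± 0.740 of TCRB-Tg Treg counts, or 0.0214% without replicate 3, against 17 counts in RAG-Foxp3 Treg and 0 in TCRd-Foxp3 Treg, at least 91.9-fold below TCRB-Tg, or 4.38-fold without replicate 3. TRAV13D-1, the TRAV13-1 group and TRAV4N-3 had no counts in TCRB-Tg Treg, at least 252-fold, 214-fold and 107-fold below RAG-Foxp3 Treg and 179-fold, 76.4-fold and 2.66-fold below TCRd-Foxp3 Treg. The last 3 are 81.9-fold without TCRd-Foxp3 Treg replicate 3 and 44.3-fold and 1.27-fold without replicate 1. The bounds for these 3 segments cover counting error alone, and a count of 0 can also follow from few TCRB-Tg Treg cells.

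In all, edgeR called 6 of 106 alpha segments in Tconv, 5 of them higher in TCRB-Tg, and 14 in Treg, 4 of them higher. The Tconv count fell to 0 without replicate 2 of each group and to 1 without replicate 1, was 14 by DESeq2 (9 higher) and was 48 with each clonotype counted once, and 6 higher and 0 lower were called with TMM. The Treg count was 3 without replicate 1, 6 without replicate 2 and 29 with each clonotype counted once; TRAV7-6 lost its call without replicate 3 and without replicate 1.

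**Figure D4:**
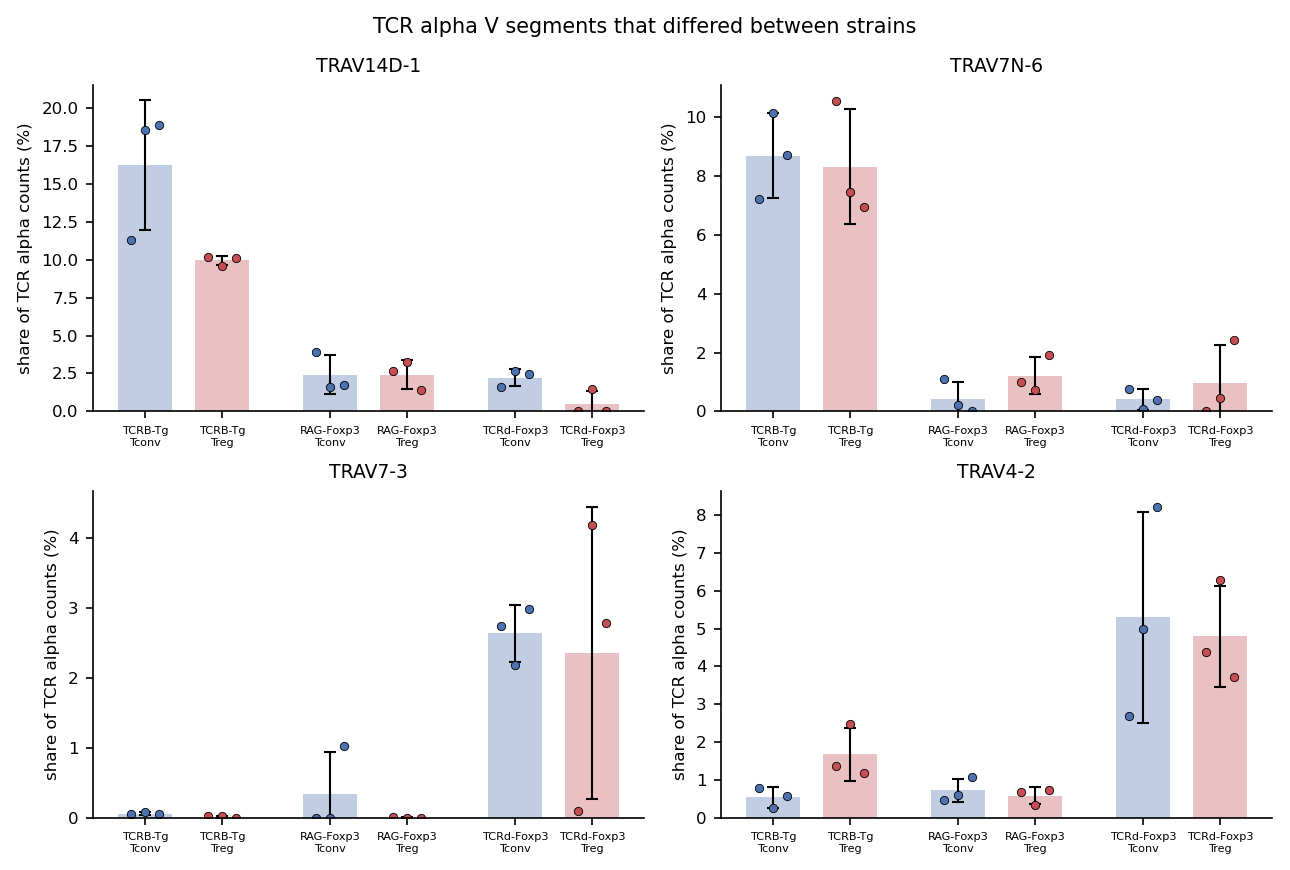
Shares of TCR alpha counts (y axis, percent) of 4 V segments in Tconv (blue) and Treg (red) of each strain; points are the 3 libraries of a group, bars the mean and whiskers the SD. TRAV14D-1 and TRAV7N-6 are highest in TCRB-Tg, and TRAV7-3 and TRAV4-2 in TCRd-Foxp3.

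RAG-Foxp3 and TCRd-Foxp3 mice both make their own alpha and beta chains. Calls between them were made in Treg, though part of the differences were also seen in Tconv. TRAV4-2 held 0.587% ± 0.224 of alpha counts in RAG-Foxp3 Treg and 4.80% ± 1.33 in TCRd-Foxp3 Treg (log2 fold change of RAG-Foxp3 over TCRd-Foxp3 -3.03, edgeR adjusted p = 0.0231), and TRAJ39 2.11% ± 0.920 and 7.26% ± 2.37 (-1.78, adjusted p = 0.0184). TRAV7-3 held 0.00554% ± 0.00345 in RAG-Foxp3 Treg against 2.35% ± 2.08 (edgeR adjusted p = 0.0231; 1.44% without TCRd-Foxp3 Treg replicate 2), and TRAV6-4 had 6 counts in 3 RAG-Foxp3 Treg libraries against 1.32% ± 1.495 (edgeR adjusted p = 0.0456). Without TCRd-Foxp3 Treg replicate 3, 1 of the 2 libraries that shared clonotypes, the latter is 0.487%. In Tconv, TRAV4-2 held 0.725% ± 0.311 in RAG-Foxp3 and 5.30% ± 2.78 in TCRd-Foxp3 (-2.87, SE 0.77, edgeR adjusted p = 0.0875). TRAV7-3 held 0.345% ± 0.595 and 2.63% ± 0.408 in Tconv, the first being 0.00162% without RAG-Foxp3 Tconv replicate 3, the other library that shared clonotypes. TRAJ39 held 3.81% ± 0.649 and 3.02% ± 0.822 there. TRAV4-2, TRAJ39 and TRAV6-4 each lost their Treg call without any 1 replicate of each group, and TRAV7-3 without replicate 1 or replicate 2. The other way, TRAV11 with TRAV11D, TRAV9N-4 and TRAV9N-3 had 0 counts in TCRd-Foxp3 Treg and were at least 144-fold, 83.02-fold and 43.5-fold higher in RAG-Foxp3 Treg. The first fell to 86.7-fold without RAG-Foxp3 Treg replicate 2 and the last to 10.1-fold without replicate 1. TRAJ28 was 1161-fold higher as a ratio of pooled shares (95% exact interval 321 to 9590), and TRAV4N-3 held 1.30% ± 0.510 against 0.0323% ± 0.0293 (edgeR adjusted p = 0.0456). These are the 9 calls of 106, with 17 at an unadjusted p under 0.05. In Tconv, edgeR called 0 alpha segments, with 3 at an unadjusted p under 0.05 and 1 call by DESeq2, and 2 were called with each clonotype counted once or without the 2 libraries that shared clonotypes. The Treg count fell to 2 without replicate 1, to 5 without replicate 2 or replicate 3, and to 4 without low-share copies, and was 15 with each clonotype counted once.

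Among beta segments, TRBV1 (log2 fold change 1.68, SE 0.25, edgeR adjusted p = 3.05e-05) and TRBV31 (0.97, SE 0.31, adjusted p = 0.0355) were higher in RAG-Foxp3 Treg than in TCRd-Foxp3 Treg. TRBV30 held 0.124% ± 0.0255 of counts in RAG-Foxp3 Treg and 0 in TCRd-Foxp3 Treg, at least 19.1-fold lower (edgeR adjusted p = 0.0355), and had 3 counts in the 3 TCRd-Foxp3 Tconv libraries. These 3 of 31 were called in Treg; in Tconv edgeR called 0, with 7 at an unadjusted p under 0.05, and 2 were called by DESeq2 or with each clonotype counted once. In Treg, DESeq2 made 1 call, and 6 were made with each clonotype counted once, where TRBV31 (0.47) was not among them. The TRBV31 value fell to 0.53 without replicate 1 and turned to -0.16 without low-share copies and with each clonotype counted once, a setting that left no call in Treg. Strain cannot be told apart from the day or batch of its libraries, which the labels do not give. For TCRd-Foxp3 it also cannot be told apart from tamoxifen, the sort on ZsGreen and the pooling of 3 mice per library. In TCRB-Tg an effect of the beta transgene cannot be told apart from that of the single functional TCR alpha allele.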

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

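Of the tests below, the carry-over and mixed-sample tests, the 3 tests on the list of 4 TRBV segments and all splits of the libraries were chosen after the result was seen. The Treg minus Tconv effect differed between strains, by edgeR's interaction test, for TRAV11 with TRAV11D (adjusted p = 6.98e-05; lower in Treg in 7 of 9 mice or pools), with effects of -7.74 in TCRB-Tg and -0.06 in RAG-Foxp3 on the log2 scale. It also differed for the TRAV13-1 group (edgeR adjusted p = 0.00462), at 0 in TCRB-Tg Treg and 2.60% against 2.30% in RAG-Foxp3 Treg and Tconv. TRAV13D-1 differed likewise (edgeR adjusted p = 0.00369), with 0 in TCRB-Tg Treg and 3.06% against 2.00% in RAG-Foxp3. TRAJ28 differed too (edgeR adjusted p = 3.38e-04), with 2 counts in TCRd-Foxp3 Treg and 2.70% against 1.14% in TCRB-Tg. Hydropathy of CDR3 alpha positions 6 and 7 moved by 0.268 in TCRB-Tg and -0.0525 in RAG-Foxp3, a difference of 0.321 with an exact p of 0.1, the smallest possible, so it was not tested in a way that could pass. Hydropathy of CDR3 beta moved by 0.162 in RAG-Foxp3 and -0.190 in TCRd-Foxp3, every pair in opposite directions, a difference of 0.352 with the same exact p of 0.1, the smallest possible.

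Libraries of different mice shared clonotypes, TCRd-Foxp3 and RAG-Foxp3 alpha libraries among them. In the 13 pairs outside TCRB-Tg that shared over 10% of the counts of 1 library, a median of 60.9% of the shared clonotypes differed at least 20-fold in share, but so did a median of 40.96% in 12 such pairs of different TCRB-Tg mice and 47.6% in 6 of the same mouse, so the test, to which these 2 sets were added after its outcome was known, does not decide on carry-over between libraries. Those 13 pairs were picked after the data were seen. Over all 34 alpha pairs outside TCRB-Tg with at least 20 shared clonotypes the median was 34.0%, and 9 pairs were over 50%. Single pairs ran from 10% to 100% in the 13, against 0.462% to 52.6% between TCRB-Tg mice and 14.1% to 77.5% in the same mouse. The highest pairs thus lie above both added sets, which the medians do not show. Shared CDR3 alpha sequences were not much shorter than unshared ones (-0.111 amino acids), which was set beforehand to count against independent formation in several mice, but that limit was wrong, since TCRB-Tg mice share many sequences at a difference of 0.128. Carry-over and independent formation therefore stay open, and no biological difference between groups was tested for this sharing.

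RAG-Foxp3 Tconv replicate 3 shared 58 alpha clonotypes, 23.5% of its counts, with TCRd-Foxp3 Treg replicate 3. TRAV6-4 and TRAV7-3 held 1.34% of its counts and 0.00481% of the other RAG-Foxp3 alpha libraries, and 98.98% of those counts lay in the shared clonotypes, which is consistent with a mixed sample. Outside them these segments held 0.0178%, against a mean of 3.00% in TCRd-Foxp3 Tconv, which argues against a wrong label on the whole library. Of the shared clonotypes 3.45% were found in 3 or more other alpha libraries at a comparable share, which argues against sequences that form in many mice. The beta libraries of the same samples shared 0 clonotypes, and where a mixture arose stays open.

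TRBV12-1, TRBV12-2, TRBV15 and TRBV16 together were higher in Treg by 12.03 points. With each clonotype counted once the difference was 7.40 points. Minor V calls for the same CDR3 and J count there as clonotypes of their own. They made up 32.9% to 53.1% of beta entries in TCRd-Foxp3 Treg and 10.3% to 20.3% in TCRd-Foxp3 Tconv. The 7.40 points alone therefore do not decide whether a few large clonotypes are the cause. With low-share copies and such calls under 5% left out and each clonotype counted once, the list still passed adjustment. Without low-share copies the difference was 12.1 points, so those copies do not account for it. Clonotypes carried over at a higher share stay in at this setting, so carry-over as a cause stays open. Without TRBV12-1 the difference was 4.49 points (2.93 without TCRd-Foxp3 Treg replicate 3) and positive in 6 of 6 mice or pools. The exact permutation p was 0.02, adjusted 0.05 over 10 tests, which does not pass, so whether TRBV12-1 acts alone stays open. The limit first set was 6 of 6 alone, which was met, and the adjusted p was asked for after the outcome was known. Selection of Treg by endogenous superantigens is a hypothesis that no test here addresses. Batch, cell number and sort purity were not tested.

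Other splits of the libraries were fitted in the same way. For TRAV, 1 of 100 splits gave as many calls as the real one (4 real, 3 at most elsewhere), and for TRAJ 3 of 100 did (1 real, 1 elsewhere), but those splits mostly break up the pairs of Treg and Tconv from 1 mouse or pool. Of 100 splits from the 256 that part every pair, the real one included, 5 gave at least the 4 TRAV calls, with up to 6, and 26 gave the 1 TRAJ call, with 1 at most, so chance is not excluded for either count. For TRBV, 5 of 100 splits gave at least the 3 real calls, with up to 5, and so did 4 of the 32 that part every pair, with up to 5, so chance is not excluded for that count; for TRBJ all 100 gave at least the real 0 (0 segments at an unadjusted p under 0.05 by edgeR, 0 calls by DESeq2), with 1 at most. For TCRB-Tg against the other strains, 1 of 84 splits of Tconv gave as many (6 real, 1 elsewhere) and 2 of 84 of Treg (14 real, 14 elsewhere), the second being the split that sets the 3 RAG-Foxp3 Treg libraries apart. The remaining comparisons have 10 splits, too few for a share under 0.05. Real counts and the highest elsewhere were 4 and 0 for alpha segments in TCRB-Tg, 2 and 1 in TCRd-Foxp3, 4 and 1 for beta segments in TCRd-Foxp3, 9 and 0 for alpha and 3 and 0 for beta segments between RAG-Foxp3 and TCRd-Foxp3 Treg, and 285 and 0 for CDR3 alpha sequences. In RAG-Foxp3 edgeR made 0 calls, with 4 alpha and 2 beta segments at an unadjusted p under 0.05 and 1 alpha and 0 beta calls by DESeq2, and all 10 splits gave at least as many, with a highest count elsewhere of 0 for alpha and 1 for beta. Between RAG-Foxp3 and TCRd-Foxp3 Tconv edgeR also made 0 calls, with 3 alpha and 7 beta segments at an unadjusted p under 0.05 and 1 and 2 calls by DESeq2, and again all 10 splits gave at least as many, with 0 and 1 elsewhere.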

How the results depend on the processing

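Alternatives that leave out low-share copies, irregular CDR3 sequences, the 2 alpha libraries in doubt or the 4 listed TRBV segments were chosen after the result was seen. Counts of calls are given first. The 4 TRAV calls became 14 with DESeq2, 2 with the replicate block, 0 without low-share copies and with each clonotype once (8 segments at an unadjusted p under 0.05 by edgeR), and 1 to 4 without 1 replicate. The TRAJ call became 0 with each clonotype once (10 at an unadjusted p under 0.05 by edgeR; DESeq2 made 1), 0 with the replicate block (3 at an unadjusted p under 0.05), 2 without the 2 alpha libraries in doubt and 0 to 1 without 1 replicate. The 3 TRBV calls became 1 to 4 without 1 replicate.

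Between RAG-Foxp3 and TCRd-Foxp3 Tconv, edgeR's 0 alpha calls (3 at an unadjusted p under 0.05) became 2 with each clonotype once, 1 with DESeq2, 1 without low-share copies and with each clonotype once, 2 without the 2 libraries in doubt and 0 to 1 without 1 replicate; the 0 beta calls (7 at an unadjusted p under 0.05) became 2 with each clonotype once, 2 with DESeq2 and 2 without low-share copies and with each clonotype once. In Treg, the 9 alpha calls became 15 with each clonotype once, 4 without low-share copies, 2 without them and with each clonotype once, and 2 to 5 without 1 replicate; the 3 beta calls became 6, 1 with DESeq2, 0 without low-share copies and with each clonotype once (3 at an unadjusted p under 0.05 by edgeR), and 1 to 2 without 1 replicate. TRBV31 reversed to -0.16 in that last-named setting. For TCRB-Tg against the other strains, the 6 Tconv calls became 48 with each clonotype once, 14 with DESeq2, 2 without low-share copies, 51 without them and with each clonotype once, and 0 to 4 without 1 replicate; the 14 Treg calls became 29 with each clonotype once and 3 to 16 without 1 replicate. The 285 CDR3 alpha calls became 5 with the replicate block, 874 without a filter and 350 to 458 without 1 replicate.

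With each clonotype once, mean TRAJ number was -0.301, the share of the 5' TRAJ segments -1.71, J-proximal TRAV -0.00979, DV calls -1.02 and the invariant NKT chain -0.0441, which stays near 0 by construction as the chain has few sequences. Without low-share copies and with each clonotype once, CDR3 alpha length was 0.00700, mean TRAJ number -0.240, 5' TRAJ segments -2.02 and DV calls -0.592, and hydropathy (0.0905) and net charge (0.0468) of alpha passed. Without low-share copies, alpha entropy was 0.00452, same-mouse overlap of alpha 0.0663 and the Morisita-Horn difference of alpha 0.133, and distinct alpha clonotypes (-1727) passed, as they did by CDR3 alone (-1467) and without the 2 libraries in doubt (-1781), where inner Cys of alpha was -0.131. Without invariant NKT and MAIT chains, length was 0.0164, mean TRAJ number -0.0882 and 5' TRAJ segments -0.136. Alpha hydropathy over 5 central residues was -0.0311, beta net charge without the 4 segments 0.0941, and alpha overlap as shared sequences 0.672.

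With the replicate block, the invariant NKT chain (-3.74), beta net charge (0.181) and the TRBV list (12.03) kept their values but did not pass adjustment. Besides these and the 3 counts of calls above, the block changed no result of the comparisons. Of 24 named segments and sequences, 14 lost their calls with it. Without 1 replicate, 1 exact test alone cannot pass adjustment. Ranges were then -4.80 to -2.10 for the invariant NKT chain, 0.169 to 0.188 for beta net charge and 9.54 to 13.4 for the TRBV list. They were 0.0890 to 0.156 for Morisita-Horn of alpha, -0.206 to 0.547 for mean TRAJ number and -0.210 to 0.691 for 5' TRAJ segments. Inner Cys of alpha ranged from -0.182 to 0.197 and beta hydropathy from -0.0470 to 0.0434.

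Of the comparisons' results under all alternatives, 274 stayed on the same side, 41 counts moved, 19 reversed, 5 newly passed and 19 no longer passed; of the named segments and sequences, 352 stayed, 122 no longer passed and 1 reversed. Alternatives that need nucleotide sequences were not run. Leaving out alpha chains does not apply to TRBV and TRBJ.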

Other observations

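All tests in this part were chosen after the result was seen. Beta net charge splits into residues: D and E per CDR3 beta were lower in Treg in 6 of 6 mice or pools (-0.104, exact permutation p = 0.005, the smallest possible, adjusted 0.025 over 10 tests), and K and R were higher in 5 of 6 (0.0769, exact permutation p = 0.02, adjusted 0.05, which does not pass). In CDR3 beta, 97.2% to 100% of the TRBV1 counts of a library carry an inner cysteine, and without TRBV1 the Treg minus Tconv difference was -0.0345 points (exact permutation p = 0.96). RAG-Foxp3 mouse 3 shared 99 beta clonotypes between Tconv and Treg, 75.3% of Tconv and 23.0% of Treg counts. In RAG-Foxp3 Tconv replicate 2, 179 beta entries carry INAE in the CDR3, on TRBV13-1, with 2.58% of counts, and in TCRd-Foxp3 Tconv replicate 3 there are 45, with 0.517%. V calls that are a minor alternative for the same CDR3 and J make up as many as 69.0% of the alpha entries of a library but at most 13.1% of its counts. For beta they make up as many as 53.1% of the entries and at most 3.33% of the counts.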
